A study of Homo sapiens with 24 samples.

How the data were processed

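P3HR1 is an established Burkitt lymphoma line that carries Epstein-Barr virus. RNA was measured on 24 Affymetrix arrays of cells that carried a doxycycline-inducible vector. Control cells made green fluorescent protein (GFP) alone, and miR-28 cells made GFP together with the miR-28 precursor. For each vector there were 2 bulk populations, A and B, and per the labels each was induced 3 times at 12 h and at 24 h. The labels give the doxycycline dose as 0.1 ug/ml in the treatment field and the design text, and as 1 ug/ml in the source field. The disagreement was left open, because all groups carry the same pair of entries. Biotin-labelled cRNA was prepared from 6 ug of total RNA per the labels' protocols.

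The deposited values are probe-set intensity on a linear scale. Per the submitters' processing notes they came from the MAS5 algorithm, with no version or settings given in the sources used here. The 2% trimmed mean of each deposited column lay between 500.07 and 500.08, so the authors' scaling to a common trimmed mean was kept. The table held 54675 probe sets, of which 62 were control probe sets and were left out of all tests. By the platform annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none listed. Symbols were updated by gene number through a RefSeq gene table, and 54 probe sets with 1 symbol were not matched and kept the older symbol. Probe sets with several symbols or none were not used for genes. No genome coordinates were used here. An array has no read depth, and the number of arrays limits the precision.

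Values were analysed as log2(intensity + 8), the pseudocount being the 10th percentile of all values, rounded. Fold changes are on that scale, which understates the change of dim genes. Each gene was represented by its probe set with the highest mean log2 intensity over the 24 arrays. The 19775 genes with a probe set were reduced to the 11380 whose mean lay above 6.108, the median of all probe sets that were not controls. A group-means model of genotype by time was fitted with limma 3.58.1 and statmod 1.5.0 in R 4.3.3, with the bulk population as a random block. The consensus correlation within populations was -0.0229. Moderated statistics from empirical Bayes were tested from both sides and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The same fit gave the difference of the miR-28 effect between times and the change with time in each genotype. A fit with 8 means of genotype, population and time tested whether the effect differed between populations. Gene lists with at least 5 measured members, 29 in all, were tested with camera at a preset correlation between genes of 0.01. Adjustment covered both times for the genotype comparisons. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were run beside it. In splits that mixed the arrays of both genotypes, the preset correlation still called a median of 3 lists at 12 h and 4 at 24 h. A list that passes with the preset correlation alone is therefore weak evidence, however small its adjusted p.

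Replicates of a group were separate inductions of 2 bulk populations, so the p-values measure the spread between arrays more than that between independently made cell populations. The random block does not guard against this, because its correlation was below 0. With the block limma called 61 genes at 12 h and 609 at 24 h (median SE 0.135). Without it limma called 52 and 531 (median SE 0.138). The letters A and B are not known to pair control and miR-28 populations. Only the comparison between populations, and values given by letter, set populations of the same letter against each other.

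The models, the filter, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls at 12 h and at 24 h, among called genes whose miR-28 population means both lay on one side of both control population means. It took the 4 largest rises and falls with time in each genotype, if both populations moved that way. It took up to 3 genes each way for the interaction and for each population difference, or the 5 smallest p where none passed. It also took the 2 members of each list with the largest moderated statistic at each time, and all measured members of the lists of reported targets and of the host gene. The genes with the smallest p at each time, the other called members of lists, and the genes of the probe-set check were named after their values were seen.

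The lists covered targets of miR-28 published from work in B-cell lymphoma cells, targets reported in other cell types, and the miR-28 host gene. They also covered the spindle checkpoint, G2/M, G1/S and replication, recombination and Fanconi repair, histones, p53 targets, pro-apoptotic and anti-apoptotic genes, MYC targets, ribosomal proteins, B-cell receptor signalling, NF-kB targets, germinal centre B cells, plasma cells, the unfolded protein response, the ATF4 response, heat shock, interferon-stimulated genes, antigen presentation, cholesterol synthesis, glycolysis, hypoxia, the respiratory chain, microRNA machinery, RAP and RAB GTPases, immediate early genes, host genes raised by viral latency proteins, and migration and adhesion. The first list was chosen at least in part on these arrays. Some list members were not analysed here.

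The procedure was tested on simulated data for the same 11380 genes. Errors were drawn independently for each gene, with a small fixed spread between populations. The counts therefore do not show how larger differences between populations, or genes that move together, would affect the calls. Of 50 genes simulated at each size in the 12 h comparison, 34 with a log2 change of -1, 21 with -0.5, 17 with 0.5 and 38 with 1 were recovered, and 6 of 11180 unchanged genes were called. For the 24 h comparison the recovered counts were 44, 25, 18 and 36 of 50, with 9 unchanged genes called. Alternatives covered the pseudocount, the filter, the scaling, the probe-set rule, the block, the unit of replication, the variance model, the arrays in the fit, and leaving out each array and each population. Leaving out 2 arrays with a high ACTB ratio, and a term for the induction number, were chosen after seeing the data. The planned tests of genes with miR-28 seed sites were not run, because no untranslated region sequences were used here.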

Results

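Expression was measured in 4 groups of 6 arrays, control and miR-28 cells after 12 h and after 24 h of induction, each group with 3 inductions of populations A and B. The median intensity per array averaged 85.17 ± 5.14 in control and 86.84 ± 4.25 in miR-28 cells at 12 h, and 84.17 ± 4.95 and 80.71 ± 5.12 at 24 h (mean ± SD, n = 6). No array quality measure differed between genotypes in 8 exact two-sided permutation tests, with a lowest p of 0.0823 (0.364 after adjustment). The ratio of 3' to 5' ACTB control intensity was above 1 on the log2 scale on 2 arrays, control population B induction 2 at 24 h (1.59) and miR-28 population B induction 2 at 12 h (1.05). Pairs of arrays of the same group had an r across genes of 0.954 to 0.969, and none held identical values. B-cell markers had a median intensity of 9220, against 65.7 for T-cell, 45.4 for myeloid, 35.7 for NK-cell and 59.2 for fibroblast and epithelial markers. Among the markers of other cell types, LCK reached 5340 and the intermediate filament gene VIM 9730. VIM was the only one of these that was called, at -0.42 (log2) at 24 h. The B-cell markers BANK1, BLNK and CD79B rose at 24 h by 0.36, 0.26 and 0.24.

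The comparison of miR-28 with control cells at 12 h asked which transcripts differed early after induction of the precursor. All arrays were of induced cells, so a difference between the populations that was present before induction cannot be told apart. In both genotype comparisons a rise or fall means higher or lower than in control cells. The smallest p belonged to the brightest of 3 probe sets annotated to SPCS3, a subunit of the signal peptidase complex, which fell by 0.81 ± 0.08 (log2 fold change ± SE, 6 against 6 arrays; limma adjusted p 5.58e-06), from a mean intensity of 5711 to 3254. The other SPCS3 probe sets gave -0.05 ± 0.11 and -0.22 ± 0.09. TBC1D4, a RAB GTPase-activating protein, fell by 0.48 ± 0.06 (adjusted p 0.000126), and the kinase gene STK35 fell by 0.63 ± 0.08 (adjusted p 0.000491). GSPT2, a translation termination factor, rose by 0.89 ± 0.11 (adjusted p 0.000339), from 758.2 to 1398. The receptor-regulated SMAD gene SMAD1 fell by 0.98 ± 0.18, from 863.8 to 427.5. RGS13, a regulator of G protein signalling in germinal centre B cells, fell by 1.01 ± 0.21, from 3774 to 1771. Other probe sets above the filter gave -0.27 ± 0.15 for TBC1D4, -0.10 ± 0.22 for STK35, -0.89 ± 0.23 for SMAD1 and -0.81 ± 0.22 for RGS13.

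In all, 25 genes rose and 36 fell at 12 h (61 of 11380; 1100 had an unadjusted p under 0.05), of which 15 and 14 changed at least 1.5-fold. The largest rises were BIN2 (2.27 ± 0.41), HCP5 (1.93 ± 0.36), CYP11B2 (1.76 ± 0.40), the G protein subunit gene GNG2 (1.48 ± 0.27), INPP1 (1.25 ± 0.29), the Notch coactivator gene MAML3 (1.19 ± 0.26), TCEAL3 (1.01 ± 0.21), the tyrosine kinase gene FER (0.94 ± 0.19), GSPT2 and LZTFL1 (0.89 ± 0.20). Other probe sets above the filter gave -0.52 ± 0.35 for GNG2, and 0.03 ± 0.20 and 0.44 ± 0.27 for FER. For LZTFL1 they gave 0.79 ± 0.47 and 0.53 ± 0.28. The largest falls were GLCE (-1.92 ± 0.34), EXO5 (-1.86 ± 0.40), CLSTN3 (-1.76 ± 0.31), KIF9-AS1 (-1.61 ± 0.33), GALNT14 (-1.04 ± 0.22), the kinetochore gene SKA1 (-1.03 ± 0.21), RGS13, SMAD1, DRC3 (-0.82 ± 0.17) and SPCS3. Many of the largest changes were in dim genes. BIN2 went from 34.06 to 205.3, and the 14 called genes with a mean intensity up to 300 had a median absolute change of 1.55, against 0.45 for the 15 above 3000. INPP1 kept its call in 10 of 44 alternatives and CYP11B2 in 16 of 44. With population means as the unit (2 against 2, few degrees of freedom) limma called 0 genes, and without the filter on low values it called 30. Without 1 array it called 26 (control A1), 36 (control A2), 39 (control B2), 38 (miR-28 A2), 39 (miR-28 A3) or 40 (miR-28 B3). Median centring of the arrays gave 12 rises and 33 falls.

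The published targets were chosen in part on these arrays, so their direction is not independent evidence. At 12 h none of the 4 passed over all genes, and 3 passed lower when adjusted over the list alone. The values were -0.35 ± 0.15 for the spindle checkpoint gene MAD2L1, -0.12 ± 0.07 for BAG1, an anti-apoptotic co-chaperone gene, -0.23 ± 0.07 for the small GTPase gene RAP1B, and -0.52 ± 0.21 for the small GTPase gene RAB23. LPP, the gene that hosts the chromosomal miR-28 locus in an intron, fell at both times, by 0.67 ± 0.12 at 12 h (adjusted p 0.0107) and by 0.81 ± 0.12 at 24 h (adjusted p 0.00021). A second LPP probe set gave -0.70 ± 0.15 and -0.80 ± 0.15, while another gave 0.10 ± 0.23 and -0.06 ± 0.23.

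Of the gene lists at 12 h, 4 fell and 2 rose with the preset correlation. Germinal centre B-cell genes fell (adjusted p 5e-05, and 0.0283 with an estimated correlation), with 1 of 22 members called, RGS13, and 2 adjusted over the list alone. G1/S and replication genes fell with a median of -0.15 (adjusted p 2.27e-10), but adjusted p = 0.0864 with an estimated correlation. Relative to the control mean at 12 h, the list mean ran from -0.097 to -0.045 on arrays of miR-28 population A. On arrays of control population B it ran from -0.158 to -0.06, so the fall did not separate the populations of the 2 genotypes. The 2 called members of 28 in the G1/S list, also 2 adjusted over the list alone, were the clamp-loader gene RFC3 (-0.54 ± 0.10) and E2F2 (-0.48 ± 0.10), a transcription factor of the G1/S transition. Other probe sets above the filter gave 0.23 ± 0.25 and -0.12 ± 0.44 for E2F2. For RFC3 they gave -0.66 ± 0.10 and 0.24 ± 0.50. Antigen presentation genes rose (adjusted p 0.00123), but adjusted p = 0.184 with an estimated correlation. HLA-C (0.38 ± 0.08) was the called member of 21, and 2 were called adjusted over the list alone, but 0 over all genes with quantile normalization. Recombination and Fanconi genes fell (adjusted p 0.00956; adjusted p = 0.184 with an estimated correlation) with 0 of 14 members called either way. Unfolded protein response genes fell (adjusted p 0.042; adjusted p = 0.119 with an estimated correlation) with 1 of 17 members called either way, EDEM1 (-0.44 ± 0.08), which acts in the degradation of misfolded glycoproteins. ATF4 response genes rose (adjusted p 0.042; adjusted p = 0.184 with an estimated correlation) with 0 of 21 called either way. After median centring the last 2 lists no longer passed, at adjusted p 0.0574 and 0.0866, and after quantile normalization the unfolded protein response did not, at 0.0511.

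The same comparison at 24 h asked what differed after the longer induction. The same SPCS3 probe set again had the smallest p and fell by 0.97 ± 0.08 (limma adjusted p 2.02e-07), from 6084 to 3104, while the other SPCS3 probe sets gave 0.00 ± 0.11 and -0.09 ± 0.09. RAB8B, a small GTPase gene of vesicle transport, fell by 0.90 ± 0.09 (adjusted p 4.06e-06), from 2733 to 1466, on its brightest probe set, while its other probe sets gave 0.11 ± 0.14 and -0.60 ± 0.23. RFC3 fell by 0.92 ± 0.10 (adjusted p 5.59e-06), from 8655 to 4556, and MAPRE1, which encodes a protein of growing microtubule ends, fell by 0.82 ± 0.09 (adjusted p 5.72e-06), from 11650 to 6573. SNUPN, an import receptor for spliceosomal particles, fell by 0.63 ± 0.06, TBC1D4 by 0.57 ± 0.06, the peroxisome biogenesis gene PEX2 by 0.70 ± 0.07 and the RNA-binding protein gene HDLBP by 0.83 ± 0.09. PIK3R3, a regulatory subunit of PI 3-kinase, rose by 0.87 ± 0.09, and RGS20, a regulator of G protein signalling, rose by 0.98 ± 0.10 (adjusted p 5.59e-06 for both).

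In all, 296 genes rose and 313 fell at 24 h (609 of 11380; 2135 had an unadjusted p under 0.05), of which 86 and 56 changed at least 1.5-fold. The largest rises were the co-stimulatory receptor gene CD28 (1.80 ± 0.45), IPMK (1.55 ± 0.42), JAML (1.48 ± 0.35), ST6GALNAC6 (1.45 ± 0.39), JUN (1.45 ± 0.37), CYP11B2 (1.44 ± 0.40), IFIT2 (1.38 ± 0.41), GNG2 (1.37 ± 0.27), MAML3 (1.34 ± 0.26) and CPNE9 (1.27 ± 0.31). The largest falls were USP2-AS1 (-1.65 ± 0.35), BGN (-1.50 ± 0.43), SKA1 (-1.47 ± 0.21), PIERCE1 (-1.29 ± 0.36), ABCB9 (-1.25 ± 0.31), SMAD1 (-1.24 ± 0.18), the co-chaperone gene DNAJA2 (-1.17 ± 0.17), WSB2 (-1.17 ± 0.16), MORF4L2-AS1 (-0.98 ± 0.27) and the 14-3-3 eta gene YWHAH (-0.98 ± 0.11). SKA1 went from 951.6 to 346.5, WSB2 from 1153 to 503.7 and YWHAH from 2489 to 1257. Several of the others were dim. The mean log2 intensity was 6.18 for CD28, 6.16 for USP2-AS1 and 6.20 for PIERCE1, close to the filter of 6.108. The 48 called genes with a mean intensity up to 300 had a median absolute change of 0.884, against 0.345 for the 190 above 3000. For DNAJA2 a second probe set of similar intensity gave 0.23 ± 0.14, against -1.17 for the one used. A second MORF4L2-AS1 probe set gave 0.43 ± 0.32, and a second GNG2 probe set 0.33 ± 0.35. Those above the filter for IPMK, JUN, IFIT2, SMAD1 and YWHAH kept the sign of the one used. IFIT2 kept its call in 16 of 44 alternatives, and BGN and PIERCE1 in 22 of 44 each. With population means as the unit (2 against 2, few degrees of freedom) limma called 0 genes, and without the filter on low values 368. Median centring of the arrays gave 395 rises and 149 falls.

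At 24 h 3 of the 4 published targets fell, over all genes and adjusted over the list alone. RAP1B fell by 0.57 ± 0.07 (limma adjusted p 1.95e-05), from 17150 ± 1470 to 11540 ± 896 (mean ± SD, n = 6). BAG1 fell by 0.40 ± 0.07 (limma adjusted p 0.000705), from 4223 ± 287 to 3188 ± 218. MAD2L1 fell by 0.52 ± 0.15 (limma adjusted p 0.0433), from 6187 ± 1390 to 4287 ± 699. The MAD2L1 call held in 19 of 45 alternatives, with -0.33 in population A alone and -0.71 in population B alone. The RAP1B call held in 43 and the BAG1 call in 42. Other probe sets gave -0.54 ± 0.10 and -0.29 ± 0.15 for MAD2L1, and -0.49 ± 0.08 and -0.51 ± 0.10 for BAG1. RAB23 had -0.19 ± 0.21 and did not pass, while its other, dimmer probe sets gave -1.38 ± 0.36 and -0.86 ± 0.45. Of the 5 measured targets reported in other cell types, TEX261 fell by 0.46 ± 0.08 (limma adjusted p 0.00172). NFE2L2 (-0.57 ± 0.19), E2F6 (-0.25 ± 0.09), N4BP1 (0.11 ± 0.10) and HOXB3 (0.18 ± 0.16) did not pass over all genes, and 3 of the 5 fell adjusted over the list alone. That list fell at 24 h (adjusted p 0.0481; adjusted p = 0.157 with an estimated correlation; 0.0654 after median centring), and at 12 h its adjusted p was 0.0639.

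**Figure D1:**
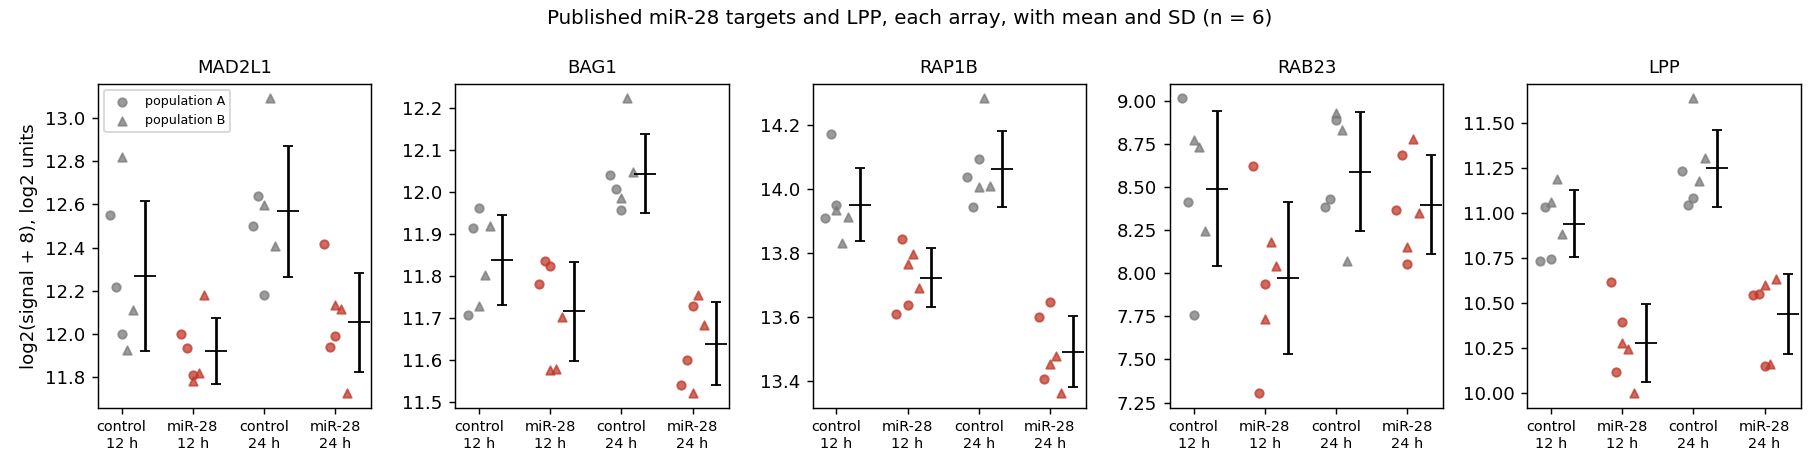
Log2(intensity + 8) of MAD2L1, BAG1, RAP1B, RAB23 and the host gene LPP on each array for control and miR-28 cells at 12 h and 24 h (points, circles for population A and triangles for B), with bars for the mean and SD of each group (n = 6). At 24 h RAP1B was lower in miR-28 cells by 0.57, BAG1 by 0.40 and LPP by 0.81.

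By the number of members called, G1/S and G2/M genes were the largest changed lists at 24 h. G1/S and replication genes fell with a median of -0.38 (adjusted p 1.31e-28, and 0.0075 with an estimated correlation). Of 28 members 15 fell and none rose, or 26 adjusted over the list alone, among them RFC3, E2F2 (-0.77 ± 0.10), the origin-binding gene ORC1 (-0.52) and the replication factor gene MCM10 (-0.55). Other probe sets above the filter gave -0.25 ± 0.25 and -0.36 ± 0.44 for E2F2, and -0.84 ± 0.10 and -0.62 ± 0.50 for RFC3. G2/M genes fell with a median of -0.29 (adjusted p 1.13e-18, and 0.00908 with an estimated correlation), 12 of 30 members over all genes and 27 adjusted over the list alone. They included the cyclin gene CCNA2 (-0.45 ± 0.09), the mitotic kinase gene AURKA (-0.42 ± 0.08), the cytokinesis gene ANLN (-0.51 ± 0.10), the transcription factor gene FOXM1 (-0.47) and CDK1 (-0.30). Spindle checkpoint genes fell (adjusted p 2.87e-07, and 0.00908 with an estimated correlation), 5 of 16 over all genes and 12 adjusted over the list alone. They included MAD2L1, CDC20 (-0.47 ± 0.11), NUF2 (-0.39), BUB1B (-0.33) and BUB1 (-0.29 ± 0.07). The list as fixed also held MXD3, a MAX-binding transcription factor gene and not a checkpoint gene, which was not called (0.29). It counts in the 16, in the list tests and in the list means. Recombination and Fanconi genes fell (adjusted p 1.58e-05, and 0.0439 with an estimated correlation), with BRCA1 (-0.50 ± 0.09) and the helicase gene BLM (-0.46 ± 0.08) called of 14, and 8 adjusted over the list alone. With median centring 10 G1/S, 4 G2/M and 1 spindle checkpoint members were called lower, and the 3 lists still passed. The replication-dependent histone genes did not pass (adjusted p 0.38), with 0 of 6 called.

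Heat shock genes fell at 24 h (adjusted p 0.000173, and 0.0075 with an estimated correlation). The 3 called members of 11, or 4 adjusted over the list alone, were the chaperone genes HSPH1 (-0.38 ± 0.09), DNAJB1 (-0.32 ± 0.07) and DNAJA1 (-0.28 ± 0.06), and 2 members were called with median centring. Germinal centre B-cell genes fell (adjusted p 0.00828), but adjusted p = 0.149 with an estimated correlation. The 5 called of 22, or 8 adjusted over the list alone, were RGS13 (-0.76 ± 0.21), SERPINA9 (-0.66 ± 0.15), TCF3 (-0.44), the histone methyltransferase gene EZH2 (-0.39 ± 0.10) and the coactivator gene POU2AF1 (-0.23). Median centring left 1 of these 5 called.

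Antigen presentation genes rose at 24 h with a median of 0.16 (adjusted p 0.000782), but adjusted p = 0.184 with an estimated correlation. HLA-B (0.49 ± 0.11), HLA-C (0.34 ± 0.08), HLA-DOA (0.42 ± 0.09) and HLA-DQA1 (0.35) were the 4 called of 21, with 8 adjusted over the list alone and 6 over all genes with quantile normalization. The class I genes HLA-B and HLA-C are closely alike in sequence, and their probe sets can share signal. Interferon-stimulated genes rose with a median of 0.40 (adjusted p 4.84e-05), but adjusted p = 0.287 with an estimated correlation. The 4 called of 22, also 4 adjusted over the list alone, were the transcription factor gene IRF9 (0.62 ± 0.11), ISG20 (0.52 ± 0.10), IFI35 (0.87) and IFIT2. B-cell receptor signalling genes rose (adjusted p 0.0201), but adjusted p = 0.184 with an estimated correlation, and their median was 0.03. The 7 called of 33, or 8 adjusted over the list alone, included the inhibitory receptor gene FCGR2B (0.56 ± 0.10), CD72 (0.42 ± 0.08) and the kinase genes SYK (0.35) and BTK (0.34). NF-kB target genes rose (adjusted p 0.0327), but adjusted p = 0.371 with an estimated correlation. The 2 called of 20, or 3 adjusted over the list alone, were the chemokine gene CCL4 (0.79 ± 0.16) and CD40 (0.28 ± 0.08). The CD40 call held in 14 of 45 alternatives. Of the NF-kB targets 1 was called with quantile normalization and 3 with median centring.

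**Figure D2:**
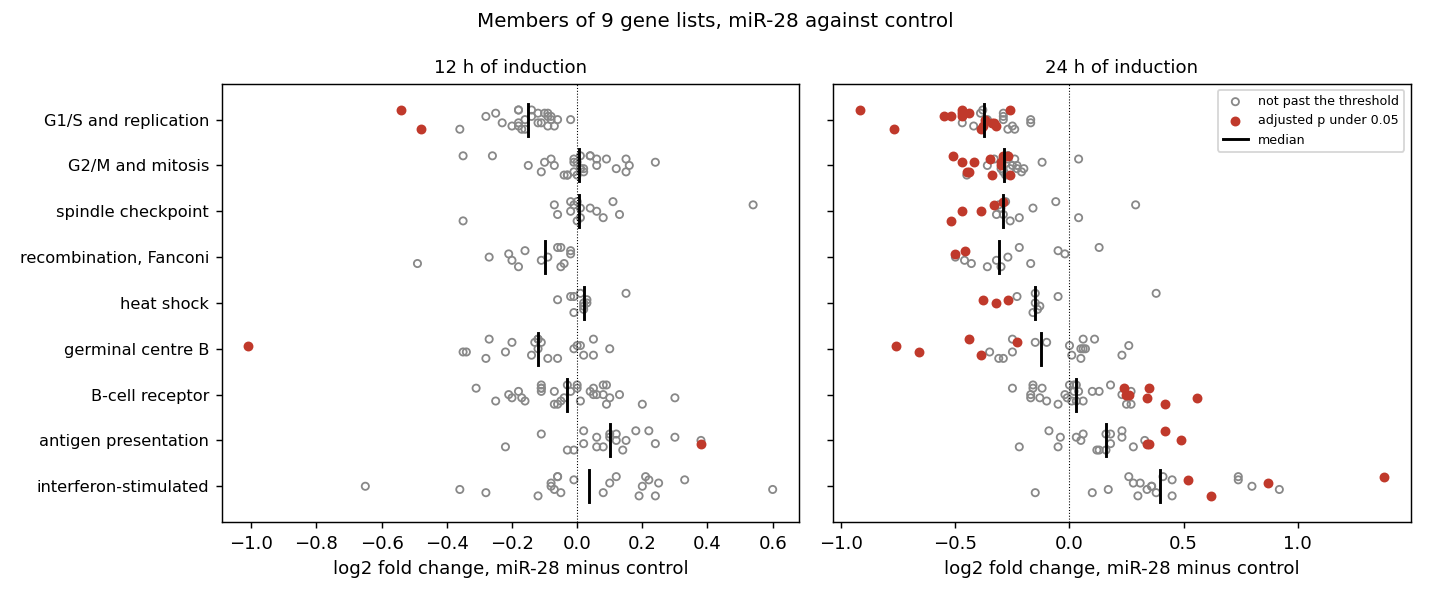
Log2 fold change of miR-28 over control cells at 12 h (left) and 24 h (right) for each measured member of 9 gene lists, with called members (adjusted p under 0.05) marked apart from the others and a bar at the median of each list. At 24 h 15 of 28 G1/S genes and 12 of 30 G2/M genes were called lower, and none higher.

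The other lists did not pass at 24 h. Their adjusted p was 0.938 for p53 targets, with the stress gene GADD45A called higher (0.65 ± 0.12; 3 up and 2 down over the list alone), 0.392 for pro-apoptotic genes, with the initiator caspase gene CASP8 higher (0.56 ± 0.10; 2 up over the list alone), and 0.813 for anti-apoptotic genes, with BAG1 lower (2 up and 2 down over the list alone). For the anti-apoptotic genes the test pointed down while the median (0.06) and the mean (0.05) were above 0. MYC targets gave 0.265 and ribosomal proteins 0.438, both with 0 genes called by limma. Plasma cell genes gave 0.452, with EDEM1 lower (1 up and 1 down over the list alone). The unfolded protein response gave 0.395, with EDEM1 (-0.42 ± 0.08) and MANF (-0.42 ± 0.08) lower and DNAJB9 (0.41) higher. The ATF4 response gave 0.473, with the mTOR inhibitor gene DDIT4 higher (0.76 ± 0.11). Cholesterol synthesis gave 0.139, glycolysis 0.542 with the hexokinase gene HK2 lower (-0.41 ± 0.11), hypoxia 0.873 with MXI1 higher (0.51 ± 0.12), and the respiratory chain 0.938 with NDUFS1 lower (-0.27 ± 0.07). Host genes raised by viral latency proteins gave 0.377, with CD40 higher, and migration and adhesion genes 0.347, with none called. For hypoxia genes the median was -0.06 and the mean 0.01, and the test pointed up. The other counts were the same over the list alone.

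The 12 h and 24 h comparisons shared no arrays but used the same 4 bulk populations, so a fixed difference between the populations would also give overlap. Of the 61 genes called at 12 h, 46 were called at 24 h, 15 up in both and 31 down in both, where independent lists of these sizes would share 0.65 and 0.99. A change in the same direction was seen at 24 h for 60 of the 61 genes, and CLSTN3 was the exception (-1.76 at 12 h, 0.42 at 24 h). At 12 h 527 of the 609 genes called at 24 h had the same sign (86.5%). Limma called 0 genes for a difference of the effect between the times, with 787 at an unadjusted p under 0.05 against 569 expected. The smallest p belonged to SMIM19 (-0.46), the separase gene ESPL1 (-0.58), CLSTN3 (2.18), TNKS (0.48) and PARVG (0.82), none of which passed (adjusted p 0.291). Without miR-28 array A1 at 12 h 1 gene was called. As lists, the effect at 24 h was lower than at 12 h for G2/M genes (adjusted p 2e-18, and 0.00747 with an estimated correlation), spindle checkpoint genes (3.81e-08, and 0.00622) and G1/S genes (3.21e-10, and 0.0417).

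In control cells 410 genes rose and 289 fell from 12 h to 24 h (699 called; 2277 at an unadjusted p under 0.05), against 364 without the filter on low values and 421 after median centring. The glycolytic regulator gene PFKFB4 rose by 1.52 ± 0.24, from 141.4 to 399.6, and the aldolase gene ALDOC fell by 1.22 ± 0.15, from 3243 to 1378. The largest rises were OXER1 (1.80), LZTS1 (1.68), CERCAM (1.61) and ASIC1 (1.59), and the largest falls UFSP1 (-1.85), CPNE9 (-1.41), MDH1B (-1.37) and KCTD21 (-1.35). OXER1 went from 105.3 to 338.8. The call held in 15 of 42 alternatives for OXER1, 17 for UFSP1, and 18 each for ASIC1 and MDH1B. G1/S genes rose, 25 of 28 members (27 adjusted over the list alone), with a median of 0.57 (adjusted p 8.46e-55, and 0.00115 with an estimated correlation). Recombination genes rose (7 of 14, 8 over the list alone; 1.61e-09, and 0.00747), as did cholesterol synthesis genes (6 of 14, 9 over the list alone; 1.23e-06, and 0.00139). NF-kB targets fell (7 of 20, 9 over the list alone; 2e-10, and 0.0136), among them NFKBIA (-0.68 ± 0.11), and so did unfolded protein response genes (6 of 17, 9 over the list alone; 5.14e-06, and 0.00115). Spindle checkpoint genes rose (3 of 16, 4 over the list alone; 0.000146, and 0.0307), and heat shock genes rose (2 of 11, 3 over the list alone; 0.00256, and 0.0136). Host genes raised by viral latency proteins fell (2 of 9, 3 over the list alone; adjusted p 0.000363; adjusted p = 0.0799 with an estimated correlation). MYC targets rose (4 of 28, 4 over the list alone; adjusted p 0.0226; adjusted p = 0.363 with an estimated correlation; 0.0623 after quantile normalization). ATF4 response genes rose, 4 up and 1 down of 21, or 7 and 1 over the list alone (adjusted p 0.0109; adjusted p = 0.0783 with an estimated correlation). With median centring the unfolded protein response had 1 member called lower, and 1 spindle checkpoint, 2 ATF4 response and 4 cholesterol synthesis genes were called higher.

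In miR-28 cells 302 genes rose and 228 fell from 12 h to 24 h (530 called; 2147 at an unadjusted p under 0.05), with 350 called without miR-28 array B1 at 12 h and 207 without the filter on low values. Median centring of the arrays gave 529 rises and 57 falls. PFKFB4 rose by 1.23 ± 0.24 and ALDOC fell by 1.30 ± 0.15. The largest rises were CLSTN3 (1.96), EXO5 (1.78), PFKFB4 and PARD3B (1.16), and the largest falls included KIR2DS1 (-1.37) and RNA45SN5 (-1.37), which reads the ribosomal RNA precursor. G1/S genes rose, 17 of 28 (23 adjusted over the list alone), with a median of 0.36 (adjusted p 4.92e-23, and 0.00747 with an estimated correlation). G2/M genes fell, 11 of 30 (16 adjusted over the list alone), with a median of -0.27 (adjusted p 1.5e-11, and 0.0317 with an estimated correlation). With median centring 2 of the 30 were called and the median was -0.17 (adjusted p 1.77e-08). NF-kB targets fell (4 of 20, 9 over the list alone; 1.28e-07, and 0.0327), as did unfolded protein response genes (1 of 17, 4 over the list alone; 2.35e-05, and 0.00139). Recombination genes rose (2 of 14, 7 over the list alone; 0.000132, and 0.0414), and so did cholesterol synthesis genes (1 of 14, 5 over the list alone; 0.0145, and 0.0414). Host genes raised by viral latency proteins fell (2 of 9, 2 over the list alone; adjusted p 0.00178; adjusted p = 0.0977 with an estimated correlation). Interferon-stimulated genes rose (2 of 22, 6 over the list alone; adjusted p 0.00135; adjusted p = 0.363 with an estimated correlation). Histone genes fell (0 of 6, 1 over the list alone; adjusted p 0.0225; adjusted p = 0.154 with an estimated correlation). Ribosomal proteins fell (0 of 20; adjusted p 0.0356; adjusted p = 0.719 with an estimated correlation), and quantile normalization turned their direction to up (0.971). With median centring 3 recombination, 4 cholesterol synthesis and 3 interferon-stimulated genes were called higher, and 0 of the latency genes lower.

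Between the genotypes, which share no arrays, 152 genes were called up with time in both and 81 down in both, where independent lists would share 10.9 and 5.79, and 0 were called in opposite directions.

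Relative to control cells at 12 h, the mean of the G1/S list was 0.59 ± 0.04 in control cells at 24 h, -0.17 ± 0.12 in miR-28 cells at 12 h and 0.19 ± 0.06 in miR-28 cells at 24 h (log2, mean ± SD over 6 arrays). The G2/M mean was 0.06 ± 0.05, 0.00 ± 0.04 and -0.24 ± 0.10 in the same groups, and the spindle checkpoint mean 0.22 ± 0.08, 0.03 ± 0.07 and -0.02 ± 0.05. At 12 h the G1/S values of miR-28 population A overlapped those of control population B.

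**Figure D3:**
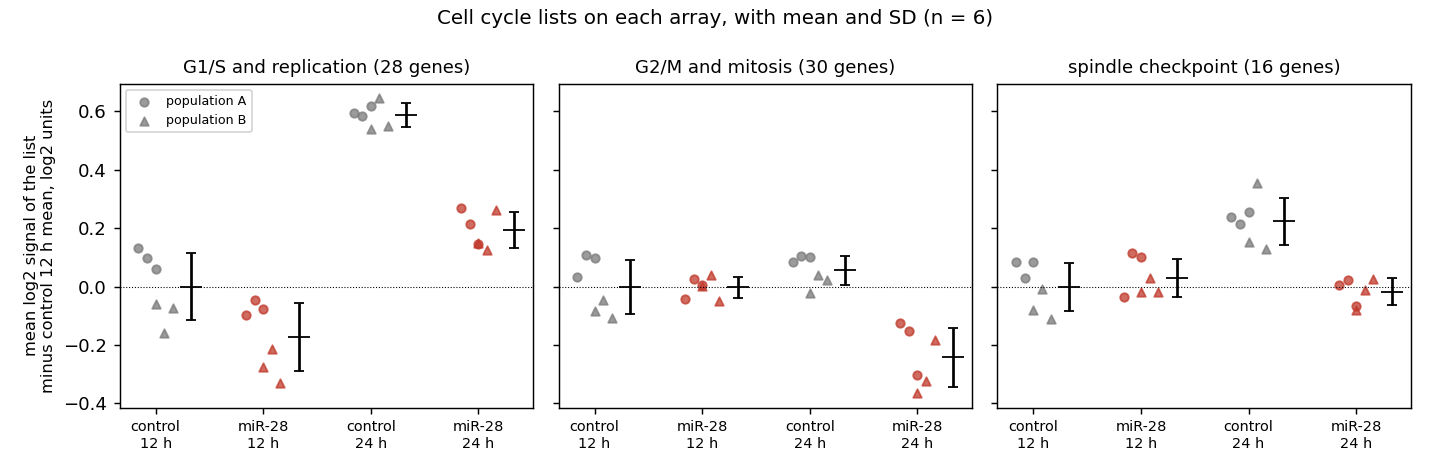
Mean log2(intensity + 8) of the members of 3 cell cycle lists on each array, relative to control cells at 12 h (points, circles for population A and triangles for B), with the mean and SD of each group (n = 6). G1/S genes lay at 0.59 in control and 0.19 in miR-28 cells at 24 h, and G2/M genes at 0.06 and -0.24.

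The effect of miR-28 was also compared between populations of the same letter, although the letters are not known to pair control and miR-28 populations, so another pairing would give other values. BCL2A1, an anti-apoptotic BCL2 relative, differed at 12 h by -1.46 ± 0.21 between population B and population A (limma adjusted p 0.0179). The difference between miR-28 and control cells was 0.75 in population A and -0.71 in population B, and at 24 h it was 0.60 and 0.43. BCL2A1 was the only gene called at 12 h, with 725 at an unadjusted p under 0.05, and limma called 0 at 24 h, with 706. At 24 h the smallest p included CARTPT (2.90), SYT9-AS1 (-1.89), TOM1 (1.84) and ETS2 (0.97), which did not pass (adjusted p 0.504). The BCL2A1 call was lost after median centring, without a filter and with the induction number as a block, where 0 genes passed. The same held without the 2 arrays with a high ACTB ratio. The count at 12 h was 0 without control array A2, A3, B1, B2 or B3 or miR-28 array A2, B2 or B3 at 12 h, 2 without miR-28 array A1 or B1 at 12 h, and 3 without miR-28 array A3 or B3 at 24 h. At 24 h the count was 1 without control array B1 or miR-28 array A1, A2 or B1 of that time. Within single letters of the same fit, 6 genes were called at 12 h in A and 6 in B, and 125 and 159 at 24 h. Of the 125, 115 had the same direction in B, and of the 159, 154 had it in A. Over all genes tested, the r between the effects in A and in B was only 0.0378 at 12 h and 0.173 at 24 h.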

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

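All tests of explanations here were chosen after the results were seen. Single arrays were compared with the other 5 of their group by the gap to the nearest value over the range of the group. Of 636 pairs of a named gene and a group, 27 had an array beyond the 5% limit of Dixon's test, which is 4.25%, against about 5% by chance. The array of control population B, induction 2, at 24 h held 7 of the 27 and was also apart in its ACTB ratio (0.632) and its GAPDH ratio (0.729). The miR-28 array B2 at 12 h held 5. Array A3 of control at 12 h and array A3 of miR-28 at 24 h lay apart from their groups on the low side in mean correlation with the other arrays of the group (0.9583 and 0.9595, with gaps of 0.778 and 0.627).

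On control array B2 at 24 h, BAG1 (0.66), EDEM1 (0.67), EZH2 (0.742), GNA13 (0.724) and ZMAT3 (0.67) were high, and CCL4 (0.653) and ITGB7 (0.648) low. On control array B3 INSIG2 was high (0.643). In control cells at 12 h, CASP8 was high on B1 (0.82), HSPH1 on B2 (0.689) and RAP1B on A2 (0.658), while PIERCE1 was low on A2 (0.67) and IPMK on A3 (0.74). On miR-28 array B2 at 12 h, BIN2 (0.682), CD40 (0.706), DNAJA2 (0.689), LZTS1 (0.887) and SLC19A1 (0.672) were low. In that group CCL4 was also low on A1 (0.656), DICER1 on A2 (0.755) and OXER1 on A3 (0.628). In miR-28 cells at 24 h, H2BC12 was low on A1 (0.744), ASIC1 on A3 (0.626), NDUFS1 on B2 (0.657), and H2AC6 (0.634) and LZTS1 (0.732) on B3, while NDUFB8 was high on B1 (0.67).

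The effect of miR-28 differed between the populations for BCL2A1 at 12 h (-1.46, log2). Of 100 splits of the arrays 11 gave at least 1 gene for that comparison (1 in the real split, highest other 1), so chance was not excluded for the count. At 24 h the real count was 0, so all 100 splits gave as many and the comparison shows nothing. The highest other split gave 31 genes, and what set its arrays apart was not tested.

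The effect differed between 24 h and 12 h for 10 lists with the preset correlation. It was lower at 24 h for G2/M genes (2e-18), spindle checkpoint genes (3.81e-08), G1/S genes (3.21e-10), heat shock genes (7.41e-05), cholesterol synthesis genes (0.0126), recombination genes (0.0221), ATF4 response genes (0.00957) and ribosomal proteins (0.0225). It was higher at 24 h for B-cell receptor signalling (0.000351) and interferon-stimulated genes (0.000141). With an estimated correlation the adjusted p was 0.0326 for B-cell receptor signalling, 0.00385 for heat shock and 0.0414 for cholesterol synthesis. It was 0.238 for recombination, 0.0528 for the ATF4 response, 0.719 for ribosomal proteins and 0.287 for interferon. Quantile normalization turned the direction for ribosomal proteins to up (adjusted p 0.396), and median centring left cholesterol synthesis at 0.0777.

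More genes were called at 24 h (609) than at 12 h (61), with none called for the difference itself. A smaller spread at 24 h is argued against by the ratio of the median residual SD at 24 h to that at 12 h, 1.01 ± 0.0421 (jackknife SE over arrays). Effects of equal size at both times are argued against by the covariance across genes of the effects in populations A and B, which was larger at 24 h by 0.0218 ± 0.00781. That covariance was 0.0271 ± 0.00574 at 24 h and 0.00538 ± 0.0053 at 12 h. At 12 h it was thus not separable from 0, and agreement of the populations over all genes was not shown. A processing batch that ran with the genotype cannot be told apart, since 0 label fields name a batch. A growth of the effect with the time of induction, which the design names, may explain the counts and stays a hypothesis.

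SPCS3 had the smallest p at both times, but from 1 of its 3 probe sets. At 24 h the brightest gave -0.97 ± 0.08, and the others 0.00 ± 0.11 and -0.09 ± 0.09. A fall of all SPCS3 transcripts by a like amount is argued against by the lower of these, -0.09. A probe set that reads another transcript, or a fall of transcripts with 1 end of the gene only, could both be candidate explanations, and 0 sequence files were used here to tell them apart.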

How the results depend on the processing

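Without a filter on low values limma called 30 genes at 12 h, 368 at 24 h, 364 for time in control cells, 207 for time in miR-28 cells and 0 for the population difference at 12 h. Median centring gave 421 for time in control cells and 0 for that population difference. Population means (2 against 2) gave 0 genes at 12 h, 0 at 24 h and 2 lists at 12 h, a fit with few degrees of freedom. Population A alone gave 0 genes at 12 h, 48 at 24 h, and 17 and 8 for time in control and miR-28 cells, and population B alone 0, 38, 34 and 2, on a smaller number of arrays. The arrays of the compared groups alone gave 39 genes at 12 h, and those of 1 time gave 10 and 1 for the population differences. Camera with an estimated correlation called 1 list at 12 h and 5 at 24 h. Without the 2 arrays with a high ACTB ratio, an alternative chosen after seeing the data, the population difference at 12 h gave 0 genes, and the other counts were 54, 606, 0, 631 and 413 genes and 5 and 9 lists. Beyond the smaller number of arrays in some fits, the cause was not tested.

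Leaving out 1 array or 1 population gave 19 to 74 genes at 12 h, 190 to 671 at 24 h, 0 to 1 for the interaction, 34 to 736 and 14 to 573 for time in control and miR-28 cells, and 0 to 3 and 0 to 1 for the population differences. The lists ranged from 4 to 7 at 12 h and from 8 to 11 at 24 h. Counts at 12 h moved by over 1.5 times without control arrays A1 (26), A2 (36) or B2 (39), miR-28 arrays A2 (38), A3 (39) or B3 (40), or populations miR-28 A (31) or miR-28 B (19). At 24 h they did so without population miR-28 A (279) or miR-28 B (190). For time in control cells they did so without control A (111) or control B (34), and for time in miR-28 cells without control A (292), miR-28 A (40), miR-28 B (14) or miR-28 array B1 at 12 h (350). The interaction gave 1 gene without population control B or miR-28 array A1 at 12 h. The population difference at 12 h gave 0 without control arrays A2, A3, B1, B2 or B3 or miR-28 arrays A2, B2 or B3 of that time, 2 without miR-28 arrays A1 or B1 of that time, and 3 without miR-28 arrays A3 or B3 at 24 h. That at 24 h gave 1 without control array B1 or miR-28 arrays A1, A2 or B1 of that time.

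The replicate labels did not pair the arrays, since same-label correlations ranged from -0.094 to 0.069 and 1 of 6 arrays matched its own label best in each pair of groups. With the replicate label as a block, limma called 61 genes at 12 h, 617 at 24 h, 0 for the interaction, and 808 and 632 with time, and 6 and 10 lists. With the number 1 to 3 as a block the population differences gave 0 and 0.

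Over 135 called results of named genes, 4878 of 5993 values under alternatives kept the call, 1115 kept the direction without it, and 0 reversed. The direction was partly fixed in advance. All 61 genes called at 12 h and 609 at 24 h had miR-28 population means on one side of both control means. Fits to population means, to 1 letter or without 1 population could therefore hardly reverse them. The alternative that tested every probe set followed the probe set already used for each gene. Population means, fitted at 12 h and 24 h and followed for 119 of the 135, called none of those. Tests of seed sites, with their alternatives, were not run. Of called genes with another probe set, 28 of 33 at 12 h and 335 of 372 at 24 h had the same direction in it, 14 and 191 of them at an unadjusted p under 0.05. The interval of the other probe set excluded the value used for 11 of the 33 and 63 of the 372. The median change was 0.54 against 0.27 in the other probe set at 12 h, and 0.42 against 0.33 at 24 h. Dim genes limit the largest folds, with a median residual SD of 0.672 up to an intensity of 300 and 0.141 above 3000.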

Other observations

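All tests of explanations here were chosen after the results were seen. Of the genes of microRNA processing and silencing, 4 of 16 were called at 24 h. DICER1, which cuts microRNA precursors, rose by 0.68 ± 0.10 (limma adjusted p 0.000279), from 3256 to 5225, and TNRC6A, a partner of Argonaute proteins, rose by 0.37 ± 0.10. The Argonaute genes AGO2 and AGO1 fell by 0.61 ± 0.14 and 0.50 ± 0.14. Of 16 members 2 rose and 2 fell, or 3 and 3 adjusted over the list alone. The list did not pass as a whole (adjusted p 0.377). Fry's test for changes in either direction gave 5.57e-10, but it also passed for other lists without a shift, such as p53 targets (1.4e-06), unfolded protein response genes (1.4e-06) and ATF4 response genes (1.03e-05), and does not set this list apart. Among RAP and RAB GTPases, RAB8B and RAP1B fell at 24 h, 2 of 23 members, with 1 up and 3 down adjusted over the list alone (adjusted p 0.139 for the list, 2.69e-19 in either direction). A second RAB8B probe set gave 0.11 ± 0.14 and another -0.60 ± 0.23. Among 14 immediate early genes JUN rose by 1.45 ± 0.37 and EGR1 fell by 0.90 ± 0.26 (adjusted p 0.601 for the list), 1 each also adjusted over the list alone. The EGR1 call held in 21 of 45 alternatives, with -0.31 in population A alone and -1.49 in population B alone.

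With time alone, hypoxia genes rose in control cells (4 of 14, 4 over the list alone; adjusted p 0.000621, and 0.0392 with an estimated correlation) and in miR-28 cells (3 of 14, 5 over the list alone; 2.31e-05, and 0.0114). Immediate early genes fell in control cells (4 of 14, 5 over the list alone; 0.000991, and 0.0208) and in miR-28 cells (0 of 14, 4 over the list alone; 0.000331, and 0.0114). Plasma cell genes fell in control cells (3 of 13, 6 over the list alone; 0.00143, and 0.0104). With median centring 1 plasma cell and 2 immediate early genes were called lower in control cells.

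The 24 h effect of miR-28 ran against the change with time in control cells. Taken between populations of different letters, so that no array was shared, their covariance across genes was -0.0126 ± 0.00414 (jackknife SE), which argues against shared control arrays as the whole cause. Without the cell cycle lists 11286 of the 11380 genes were left, and the slope of the effect on the control change was -0.347 ± 0.0955. Over all genes it was -0.36 ± 0.0901. The listed genes alone therefore did not carry the slope. Other cell cycle genes, such as SKA1 and ESPL1, stayed in, so cell cycle genes as a whole were not tested. A smaller change with time in miR-28 cells may be a candidate explanation, but the slope of their change on that of control cells was 0.823 ± 0.207 and does not tell.

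Counts were compared with 100 splits of the same arrays. When single arrays were exchanged, chance was excluded for the genes called at 12 h (61, highest other split 2), at 24 h (609, highest other 3), with time in control cells (699, highest other 99) and with time in miR-28 cells (530, highest other 2), where 1 of 100 splits, the real one, gave as many. For the interaction the real count was 0 (highest other 1), so all 100 splits gave as many and the comparison shows nothing. For lists called it was not excluded, since 15 splits gave as many at 12 h (6 lists, highest other 12) and 5 at 24 h (11 lists, highest other 13). The median of the other splits was 3 lists at 12 h and 4 at 24 h. Of the 3 ways to split the 4 populations into 2 and 2, the real one gave 61 and 609 genes, and the others at most 1 at 12 h and 0 at 24 h. With so few, no share under 5% can be reached, so the exclusion at 12 h and 24 h holds for single arrays and not for the populations.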
